A study of Homo sapiens with 2 samples.

How the data were processed

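Gene expression was measured in T47D, an established oestrogen receptor positive human breast cancer cell line of luminal type, carrying either a negative control lentivirus (NC) or a lentivirus with a short hairpin RNA against TRPS1 (shTRPS1). Each group had 1 array, so the study held 2 arrays and no replicates. Per the labels' protocols, total RNA was converted to cDNA, labelled with the dye Cy3 and hybridised to one-colour NimbleGen whole human genome arrays.

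The values used were the intensities that the authors deposited for each array, on a linear scale, with 1 value per transcript accession (called a feature here). The submitters' processing notes name RMA, a method that corrects background, normalizes by quantiles and summarises the probes of a transcript; its version, the exact steps and the genome build of the array design are not given in the sources used here. The design written before the data were examined assumed log2 values, so log2 of the deposited intensities was taken first. Intensities ran from 50.0 to 62667 in the NC array and from 50.1 to 62395 in the shTRPS1 array, and their medians were 402 and 414. No intensity was under 50 on either array, so dim features appear to have been left out before deposit, by a rule that no source used here states. A transcript under 50 on either array is therefore not analysed here. A second table of the series has 8 sample columns with template names that match no label. Its title says that some genes were excluded from sample tables, without the rule used. None of its values was used, only its list of 18881 feature accessions. All of these were also in the value table and made up 65.2% of its features.

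Of the 28973 features, 12598 received 1 gene symbol and none received several. A symbol came from the RefSeq accession in the GRCh38.p14 gene table where it was found there, and otherwise from the platform annotation. The platform annotation held 12145 of these features, and a further 453 were named by RefSeq accession alone. The remaining 16375 features, among them cDNA clone and withdrawn RefSeq accessions, were not named and entered no gene count. The named features belonged to 11564 genes, of which 848 had more than 1 feature. A gene was represented by its feature with the highest mean log2 value over both arrays. No genomic coordinates are printed because the build of the array design was not given.

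The background level of an array was the 95th percentile of its 60 olfactory receptor features, a gene family with no known role in breast epithelium. It was an intensity of 397 in the NC array and 325 in the shTRPS1 array. A gene counted as above background if at least 1 array exceeded its level, which held for 6949 genes. A gene was called higher or lower in the shTRPS1 array if its log2 values differed by at least 1, which is 2-fold, and it was above background. Where 1 array was not above background, the dim value was replaced by that array's background level and the difference is given as "at least"; where this gave less than 1, no fold is printed. Because there were no replicates, no test between the groups was possible and no p-value is given: every difference compares these 2 arrays, and the number of arrays limits the precision.

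For 34 gene lists fixed before the data were examined, the median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these 2 arrays only, since genes are not independent replicates. With 34 lists, 1.7 are expected outside the central 95% by the definition of that range, if the members of a list vary independently. The genes named in the text were TRPS1, the 12 genes with the largest measured log2 difference upward and the 12 with the largest downward, at least 2-fold and above background, whose features above background all went the same way (without LOC and orf symbols; where 1 array was dim this order is not established), up to 3 members of each list in each direction that were called, and 12 genes of prior interest whatever their values (ESR1, GATA3, FOXA1, CDH1, VIM, ZEB2, TP63, SUZ12, CCN1, CCN2, PGR and MKI67). Of the latter, ZEB2, TP63 and CCN2 had no named feature in the values used. Genes named outside this rule are marked as chosen after their values were seen. Some genes that entered the counts are not reported here by name, even where the rule would name them.

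Alternatives were median-centred, quantile-normalized and loess-corrected values (lowess span 0.4), the mean over features or the feature with the median difference, other background filters, thresholds of 1.5-fold and 3-fold, the feature list of the second table, unmatched random lists and the mean in place of the median. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The procedure was tested on simulated data for the comparison of shTRPS1 with NC over 11564 genes, with noise set, in each of 20 expression bins, to the median absolute deviation observed between the arrays. The planted genes were bright ones, with a mean log2 value over 10, so recovery among dim genes was not tested. Of 50 genes raised by 1.5 on the log2 scale 42 were called, of 50 lowered by 1.5 on that scale 48, and of 50 changed by 2.5 in each direction all 50. Among the 11364 genes without such a change, 267 were called. A planted list of 25 genes shifted by 0.5 lay at the 100th percentile, and 14 of 200 lists of 25 genes drawn from those 11364, 7%, lay outside the central 95%. The noise was drawn independently for each gene from a normal distribution, so the simulation does not cover lists whose members vary together.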

Results

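The data comprised 1 array of T47D cells with the control lentivirus (NC) and 1 array of T47D cells with the lentivirus against TRPS1 (shTRPS1). TRPS1 encodes a GATA-type zinc finger protein that acts mainly as a transcriptional repressor and is abundant in luminal breast epithelium. The comparison addressed which transcripts differ when TRPS1 is knocked down. The 2 arrays correlated at r = 0.961 over the log2 values of 28973 features, a correlation across features that are not independent replicates. The median log2 difference over all features, shTRPS1 minus NC, was 0.04.

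The targeted transcript itself was only slightly lower. TRPS1 (feature NM_014112) had an intensity of 726 in the NC array and 603 in the array labelled shTRPS1, a log2 difference of -0.27 or 17.0% lower. Both values were above background, whose levels were 397 in the NC array and 325 in the shTRPS1 array. This difference lay at the 21.2th percentile of genes of like signal, whose central 95% ran from -0.90 to 0.97, so it was smaller than the spread between genes of that brightness. TRPS1 had 1 named feature, and the position of its probes relative to the hairpin's target site is not given in the sources used here. The measured direction goes with the label, but its size does not set TRPS1 apart from other genes, and all directions below rest on the array labelled shTRPS1.

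Of the 6949 genes above background, 263 were at least 2-fold higher and 165 at least 2-fold lower in the shTRPS1 array by their measured intensities, together 428 genes or 6.16%. Both arrays were above background for 81 of the higher and 77 of the lower genes. The other 182 higher and 88 lower genes had a dim array. Of these, 23 higher and 24 lower genes were at least 2-fold apart by the bound too, and 52 of the higher genes had no bound, since their shTRPS1 value did not exceed the background level of the NC array. None of these differences has a replicate check. In the simulation, with noise set from the spread between these same arrays, 267 of 11364 genes with no planted 2-fold change passed the same rule. That base includes genes not above background, so the observed count to set beside it is 428 of 11564 genes. The simulated noise was normal and scaled to the middle of the observed differences, so real noise can give more extreme values. The 2 counts therefore do not show how many calls exceed noise. Among the 60 olfactory receptor features 4, or 6.67%, were at least 2-fold apart, and the SD of their log2 differences was 0.63. That share was taken without a background filter. The gene counts to set beside it, also without a filter, are 545 higher and 440 lower of 11564. The SD over genes narrowed from 0.74 at a mean log2 intensity of 7 to 8 to 0.37 above 12.

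Technical agreement could be judged within the arrays from genes with several features. In 519 genes with at least 2 features above background, the log2 differences of the 2 brightest features correlated at r = 0.486 across genes. Of the 12 called genes among them, the next feature went the same way in 9 and was itself at least 2-fold apart that way in 5. These 5 were ATF4, HYAL1, MID1, SMOX and TNFRSF18, and the next feature went the other way in AGER, OGG1 and USH1C; these genes, ATF4 apart, were chosen after their values were seen. ATF4, a transcription factor of the integrated stress response, had log2 differences of 1.08 and 1.60. MUC1, a mucin of the luminal epithelial surface, had differences of 1.34 and 0.97.

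Among genes with both arrays above background, the largest difference upward was in SLC7A8, a neutral amino acid transporter, which was 4.99-fold higher, from 408 to 2036. Its NC value was close to that array's background level of 397. S100A2, a calcium-binding protein typical of basal epithelium, had an intensity of 228 in the NC array, which is not above background, and 1906 in the shTRPS1 array, so that it was at least 4.80-fold higher. AKAP10, an anchoring protein for protein kinase A, was at least 2.74-fold higher, ACTL7A, an actin-like gene known from testis, at least 1.98-fold, and the immediate early gene FOSB at least 1.94-fold. STARD13 was at least 1.42-fold higher, HCAR3 at least 1.21-fold, FOS at least 1.21-fold, IPO11 at least 1.09-fold and KHDC3L at least 1.02-fold. B3GNT9 and UGT1A1 were also named by the rule, at 391 and 366 in the shTRPS1 array against 56.3 and 71.6 in the NC array. Both exceeded the background of the shTRPS1 array but not that of the NC array, so no fold is given. UGT1A1 shares most of its exons with the other UGT1A transcripts, which the feature may also detect.

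Among genes with both arrays above background, the largest differences downward were in SUSD2 and AQP3. SUSD2, a sushi domain membrane protein, was 10.7-fold lower, from 3843 to 361, and AQP3, a water and glycerol channel, was 4.95-fold lower, from 3975 to 804. The shTRPS1 value of SUSD2 was close to that array's background level of 325. The other 10 genes that the rule named downward were not above background in the shTRPS1 array, so their order is not established. Among them ATP8B3 was at least 2.81-fold lower, CD70, a TNF family ligand, at least 2.56-fold, and ZAP70, a T-cell receptor kinase, at least 2.22-fold, with an intensity of 721 in the NC array. CTAG2, a cancer-testis antigen, was at least 2.09-fold lower, FKBP1B at least 1.92-fold and the potassium channel KCNN4 at least 1.90-fold. SLAMF1, AP3B2, CAMKV and WNT9A were at least 1.57-fold, 1.47-fold, 1.34-fold and 1.31-fold lower.

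**Figure D1:**
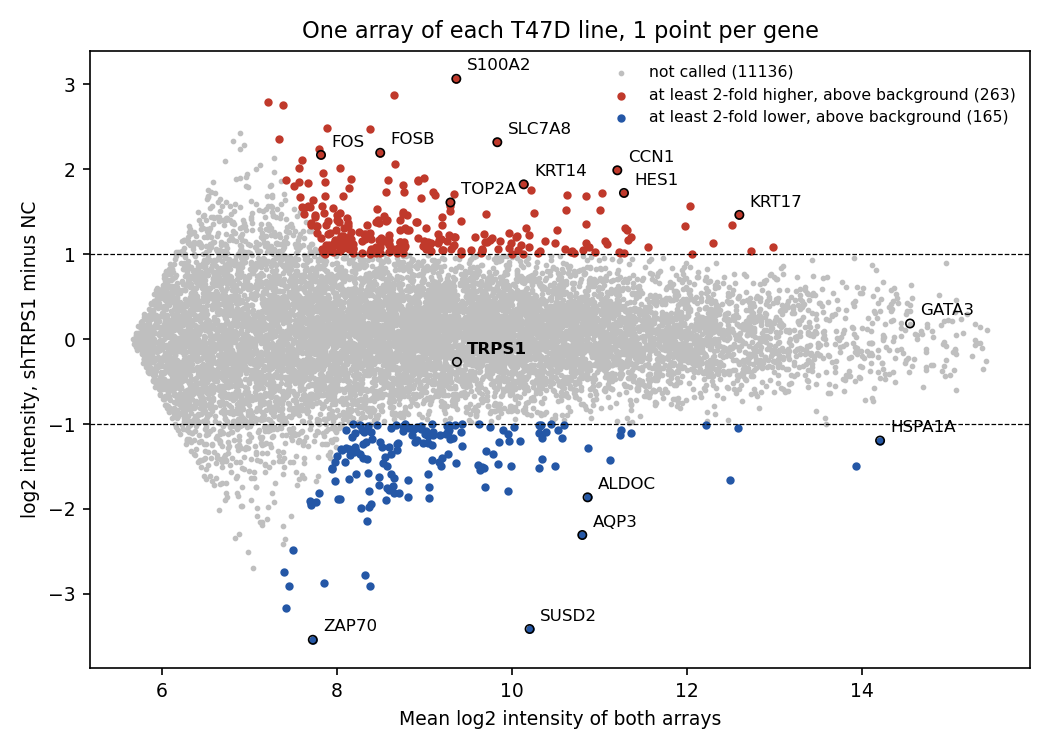
Mean log2 intensity of both arrays (x axis) against the log2 difference shTRPS1 minus NC (y axis), 1 point per gene; red and blue points are the 263 higher and 165 lower genes, grey points are not called, dashed lines mark 2-fold. TRPS1 lies at -0.27 within the grey cloud, while SUSD2, AQP3, SLC7A8 and CCN1 stand apart at signals above background on both arrays. SLC7A8 in the NC array and SUSD2 in the shTRPS1 array were only slightly above it.

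Of the 34 fixed gene lists, 6 lay above and 4 below the central 95% of matched random lists, against 1.7 expected outside by the definition of the range. That expectation holds for randomly drawn genes, whereas members of a real list can vary together. The 34 lists held 713 different measured genes, and some genes belong to several lists. Over the few members with features in the second table, YAP and TAZ targets (2 members), immediate early genes (1), replication (7), interferon (4) and fatty acid genes (3) lay inside the range.

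YAP and TAZ target genes, which respond to Hippo signalling, and immediate early genes had the largest positive medians. The median over 18 measured YAP and TAZ targets was 0.64, above all 10000 random lists, and 14 of the 18 differences were positive. Of these targets 3 were called higher and 0 lower: CCN1, a secreted matrix protein, was 3.97-fold higher, from 1184 to 4697, FJX1 was 2.43-fold higher and ARHGEF17 was 2.20-fold higher. Only 8 of the 18 were above background. The median over 27 immediate early genes was 0.63, also above all 10000 random lists, with 6 called higher and 0 lower. These 6 were FOSB, FOS, CCN1, KLF6, ZFP36 and ATF3, and KLF6, a Krüppel-like factor, was 3.38-fold higher, from 649 to 2195. KLF6 and ZFP36 were chosen after their values were seen. CCN1 belongs to both lists.

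Genes of mitosis and of DNA replication were higher. The median over 42 mitotic genes was 0.54, above all 10000 random lists, with 39 positive differences, 6 genes called higher and 0 lower. Over the 24 members with both arrays above background it was 0.33 at the 99.8th percentile. TOP2A, the DNA topoisomerase of dividing cells, was at least 2.77-fold higher, from 360 to 1098. ANLN, a cytokinesis protein, was at least 1.19-fold higher, and DLGAP5, a spindle protein, read 107 and 342, of which only the second exceeded its background. AURKA and CCNB2, the mitotic kinase and cyclin, were 2.19-fold and 2.09-fold higher with both arrays above background; they were chosen after their values were seen. MKI67, a proliferation marker, read 89.3 and 174, below background on both arrays. The median over 43 replication genes was 0.31, which 3 of 10000 random lists reached, and POLA1, the catalytic subunit of DNA polymerase alpha, was the only member called, at least 1.29-fold higher. With the feature of median difference in place of the brightest, the replication list had a median of 0.18 and lay just inside the range, and over 7 members in the second table it had 0.11 at the 67.4th percentile.

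Unfolded protein response and interferon genes also lay above the range, by less. The 22 unfolded protein response genes had a median of 0.28 at the 98.5th percentile, and 3 were called higher: PPP1R15A, a phosphatase subunit of the stress response, was 2.23-fold higher, ATF4 was 2.12-fold higher and ATF3 was at least 1.39-fold higher. The 34 interferon response genes had a median of 0.25 at the 98.4th percentile, with OAS3 2.29-fold higher, STAT2 at least 1.44-fold higher and EIF2AK2, the double-stranded RNA kinase, at least 1.07-fold higher. Both lists came inside the range over their members above background alone, at the 93.9th and 85.2th percentile. ATF3 was under 2-fold after median-centring, quantile normalization and loess.

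Ribosomal protein and fatty acid genes were lower, and the histone list lay below the range with members in both directions. The median over 52 ribosomal protein genes was -0.25, below all 10000 random lists, with 42 negative differences and no gene called in either direction. RPS20, chosen after its values were seen, had a log2 difference of -0.93. The 19 fatty acid metabolism genes had a median of -0.32 at the 0.42th percentile, with 15 negative differences and no call. The 30 clustered histone genes had a median of -0.19 at the 0.64th percentile, with 17 negative and 13 positive differences, while H2BC21, the only one called, read 174 and 355 and was under 2-fold after any of the 3 rescalings. Against random lists matched on gene span as well, the histone list lay at the 19.7th percentile, and over the 2 members in the second table its median was 0.39. Ribosomal protein genes have many processed pseudogenes and histone genes near-identical copies, so these features can detect more than 1 locus.

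The median over 28 luminal identity genes was 0.16 at the 91.4th percentile, against 0.19 at the 98.0th percentile after quantile normalization and a mean of 0.31 at the 99.9th, both above the range. GATA3 (log2 difference 0.18), FOXA1 (0.07) and ESR1 (0.11), the core luminal transcription factors, were all under 2-fold. GATA3 and FOXA1 were bright, whereas ESR1 read 541 and 582, not far above the background levels of 397 and 325. Its small difference therefore says little about a change in ESR1. MUC1 was 2.53-fold higher and TFAP2B 2.25-fold higher, and no luminal gene was called lower. Oestrogen receptor targets had a median of 0.13 at the 84.4th percentile, with FOS called higher and RERG and CELSR2 lower, RERG by at least 1.95-fold and CELSR2 by 2.29-fold. PGR, the progesterone receptor, had a log2 difference of -0.35, from 549 to 431, and was also not far above background.

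In the basal and myoepithelial list 4 of 17 measured genes were called higher and 0 lower, while the list median was 0.12 at the 68.9th percentile. KRT14 was 3.54-fold higher, from 598 to 2113, and KRT17 was 2.76-fold higher, from 3735 to 10294, and S100A2 was among the 4 as well. KRT5, KRT6A and KRT16, basal keratins chosen after their values were seen, had log2 differences of -0.27, -0.80 and -0.60. The list lay above the range in 3 alternatives, with a median of 0.38 at the 99.4th percentile when the features of a gene were averaged, 0.48 at the 99.1th over 7 members in the second table, and a mean of 0.41 at the 99.8th. With both arrays above background its median was 0.05 at the 47.3th percentile over 11 members. Keratin transcripts are similar in sequence, so signal from related keratins in these features was not excluded.

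Mesenchymal genes had a median of 0.29 at the 93.8th percentile over 17 measured members, of 36 listed. COL5A1, a fibrillar collagen, was at least 2.73-fold higher, THBS1, thrombospondin, 2.48-fold higher and MMP2 read 171 and 374, while COL1A1 and TGFBI, the latter chosen after its values were seen, were also called higher. THY1 was at least 1.99-fold lower. VIM, vimentin, had a log2 difference of 0.67. The list median depended on the members taken: it was 0.68 at the 100.0th percentile over 12 members above background on at least 1 array, 0.41 at the 99.4th over 8 with both arrays above background, 0.999 at the 100th over 6 with features in the second table, and 0.10 at the 56.7th over 12 with features outside it. Epithelial junction genes had a median of 0.14 at the 85.3th percentile with no call, and CDH1, E-cadherin, had a log2 difference of 0.11.

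The list of reported TRPS1 partners and targets had a median of 0.20 at the 88.7th percentile and no called member among 18 measured. Over 15 members with features outside the second table its median was 0.40 at the 99.0th percentile, above the range, and over 12 with both arrays above background 0.10 at the 66.0th. SUZ12, a Polycomb subunit, had a log2 difference of -0.25. p53 targets lay close to the edge of the range, with a median of 0.30 at the 97.4th percentile and no call, and were above the range in 7 of the alternatives, among them loess at the 99.0th percentile. Heat shock genes lay close to the other edge, with -0.20 at the 3.31th percentile, and below the range at the 1.59th after quantile normalization. HSPA1A, an inducible chaperone with a near-identical copy, was 2.29-fold lower, from 28598 to 12498. Oxidative phosphorylation genes had a median of -0.07 at the 12.6th percentile, with SDHC, which read 170 and 355, the only call; over 36 members above background the median was -0.14 at the 1.25th percentile, below the range. Hypoxia and glycolysis genes had a median of 0.09 at the 61.7th percentile and a mean of -0.06, of opposite sign, with the glycolytic enzymes ALDOC 3.64-fold lower and ENO2 at least 1.85-fold lower. Sterol synthesis genes had a median of 0.01 at the 36.3th percentile, with 2 called higher, among them SC5D, which read 174 and 377.

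For the other signalling lists the median stayed inside the range. The 12 Wnt genes (0.30, 91.6th percentile) included RNF43, which read 116 and 337, and ASCL2, 2.10-fold lower. The 13 Notch genes (0.29, 94.0th percentile) included HES1, a Notch-responsive repressor, which was 3.30-fold higher, from 1369 to 4514. NF-kB and cytokine genes (-0.05, 27.8th percentile) included LIF, at least 1.59-fold higher, and TRAF1, at least 2.25-fold lower. Cartilage and bone genes (-0.19, 12.4th percentile) included MATN3, at least 1.94-fold higher, PTH1R, at least 1.57-fold lower, and COL9A2, lower from 971 to 485; the median of this list was 0.55 over 4 members with features outside the second table and -0.32 over 7 in it. Polycomb-bound developmental genes (median -0.01, 35.9th percentile, mean 0.02 of opposite sign) included HOXA10, 2.08-fold lower, and apoptosis regulators (0.02, 41.4th percentile) included MCL1, 2.08-fold higher but under 2-fold after quantile normalization and loess. TGF-beta and BMP response genes (-0.09, 20.8th percentile), DNA repair genes (0.17, 83.6th percentile) and antigen presentation genes (0.10, 74.1th percentile, but a mean of 0.28 above the range at the 98.6th) had no called member. Under at least 1 alternative the sign of the median also turned, inside the range, for the apoptosis, Polycomb, TGF-beta and BMP, antigen presentation, oestrogen, sterol, endothelial and TRPS1 partner lists, so no direction is given for these. Housekeeping genes had a median of 0.05 at the 54.9th percentile, with 0 of 28 called.

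Few markers of other cell types had a named feature with values. Of 13 fibroblast, 12 endothelial and 17 leukocyte markers, 2, 5 and 5 had values, with medians of -0.11, -0.05 and -0.57 at the 33.3th, 43.1th and 7.21th percentile, and no leukocyte marker was above background. Against unmatched random lists the leukocyte list lay below the range, at the 1.65th percentile. The 2 fibroblast markers were COL1A1 and THY1. Genes of HEK293 cells, the usual lentivirus packaging line, had a median of -0.66 at the 0.17th percentile over 6 of 14 listed, with GAL, galanin, 2.13-fold lower, from 1953 to 916. Whether T47D cells express these genes themselves was not tested, so this median does not show carry-over of packaging cells.

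**Figure D2:**
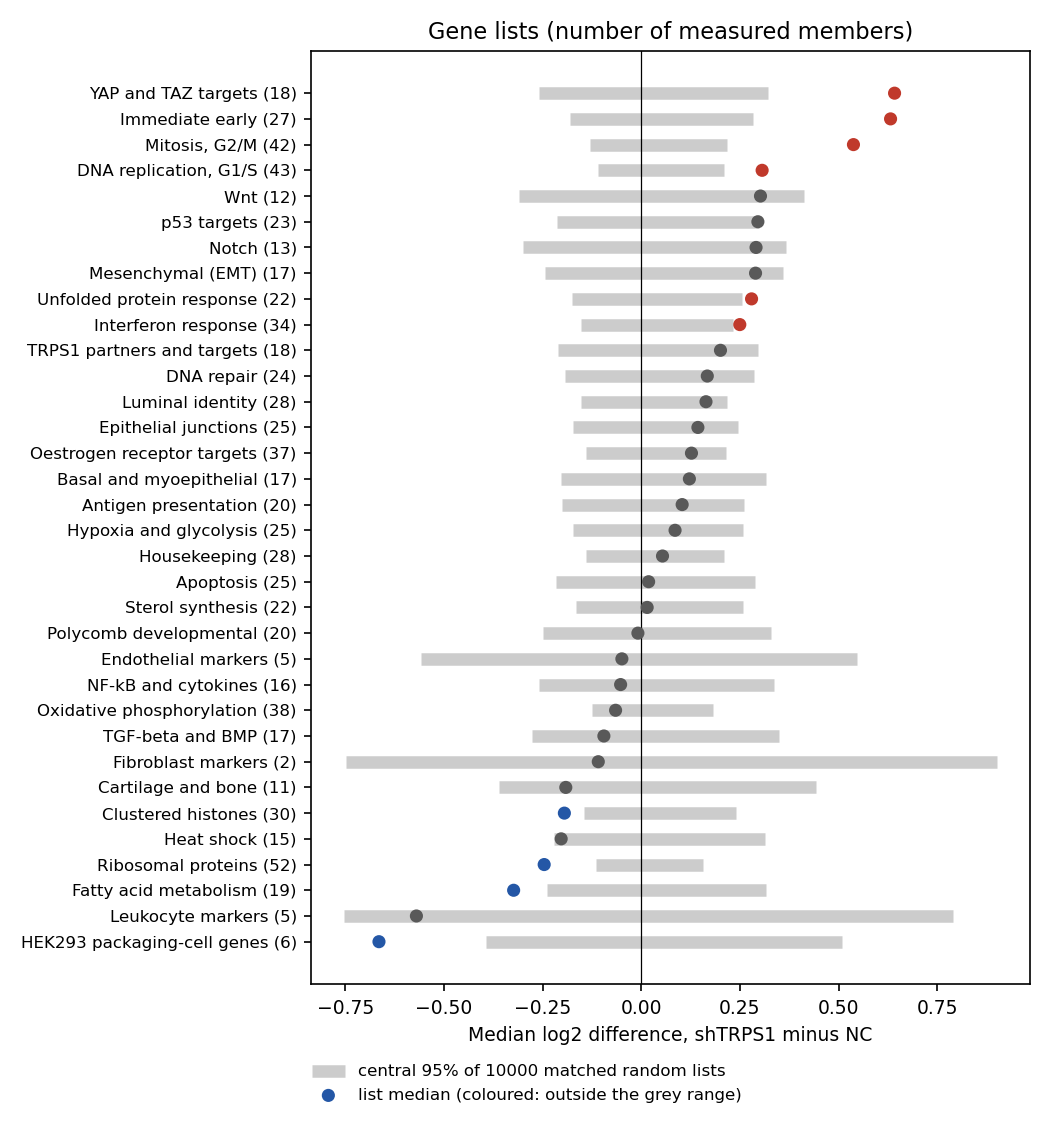
Median log2 difference, shTRPS1 minus NC (x axis), of each of the 34 gene lists (y axis, number of measured members in parentheses); grey bars span the central 95% of 10000 random lists matched on expression. Red and blue points mark the 6 lists above and 4 below that range, with YAP and TAZ targets at 0.64 and ribosomal proteins at -0.25.

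**Figure D3:**
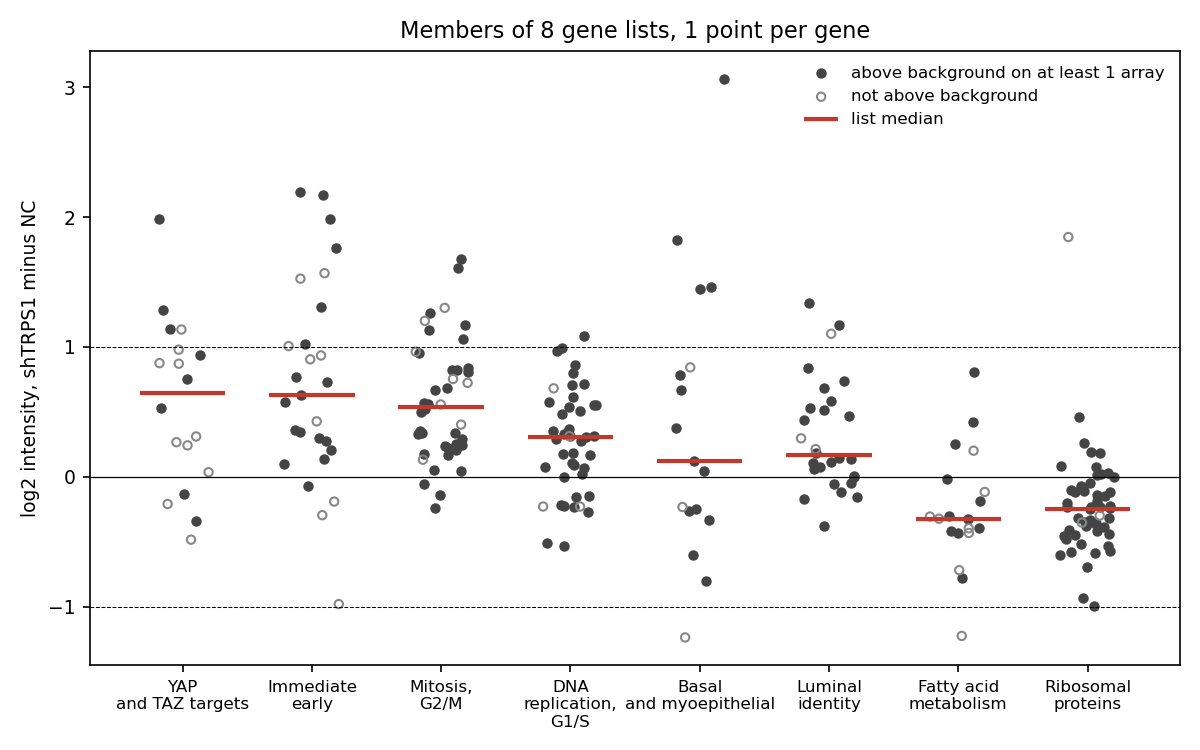
Log2 difference, shTRPS1 minus NC (y axis), of each measured member of 8 lists (x axis); filled points were above background on at least 1 array, open points on neither, red lines are list medians and dashed lines mark 2-fold. The ribosomal protein genes lay around a median of -0.25 with none called, whereas the basal list held 4 called genes and a median of 0.12.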

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

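The tests of the TRPS1 difference, the removal of the shared gene, the use of genes with both arrays above background against dim members, the matching on gene span and the 3 lists of short transcripts were chosen after the patterns they address were seen; for TRPS1 and the dim members the tested values themselves had been seen.

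Features without a gene name were left out of the comparison but carried signal as well. Of 16375 such features 9197 were above background, and 376 of these were at least 2-fold higher and 293 at least 2-fold lower in the shTRPS1 array than in the control array, together 7.27% against 6.16% of named genes. The unnamed accessions with the largest measured differences upward were BC064803, at 86.4 in the NC array and 1199 in the shTRPS1 array, and NM_144782, at 136 and 1413. Downward they were AK096139, at 593 and 50.5, and XM_929759, at 654 and 59.4. In each of these the lower value was not above its array's background level, 397 for NC and 325 for shTRPS1. Their order and rank are therefore not established.

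The small difference in TRPS1 in a knockdown of TRPS1 is a pattern to look at again. At the 21.2th percentile of genes of like signal, the difference of -0.27 can arise from array noise alone. A loss of transcript would give the same direction. The size of such a loss cannot be set here, since both values were not far above background. An exchange of the 2 labels would put TRPS1 higher in the array labelled shTRPS1. TRPS1 was lower there, but within the spread of genes of like signal, so this value cannot tell whether the labels were exchanged. A knockdown that acts mainly on the protein was not tested. A probe upstream of the cleavage site, or transcripts lost below the deposit threshold, cannot be examined with these values.

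YAP and TAZ targets and immediate early genes were higher together. An intensity-dependent normalization trend as the whole cause is argued against by the medians, 0.59 and 0.57 after loess against 0.64 and 0.63 before. The list nearer to the middle then lay at the 100th percentile. That percentile decides little, since the random lists were already matched on mean expression. Both lists share 1 measured gene, CCN1, and without it the lower of the 2 lists lay at the 99.85th percentile, although removing 1 member can move a median only a little. Dim members as the whole cause are argued against by members with both arrays above background, where the lower list lay at the 99.98th percentile, while the 100th percentile over members above background on either array decides nothing, since a large difference itself can bring a gene in. A difference in density, serum or handling between the 2 cultures could raise both lists and, with 1 array per group, is confounded with the hairpin, as is a direct effect of TRPS1 on YAP-dependent transcription.

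Mitotic and replication genes were higher while ribosomal protein genes were lower. A trend with intensity as the whole cause is argued against by the medians after loess. These were 0.48 for mitotic, 0.24 for replication and -0.25 for ribosomal protein genes. The list nearest to the middle, replication, then lay at the 99.88th percentile. That percentile decides little, since the random lists were already matched on mean expression. Gene span is argued against by matching on it as well, where replication lay at the 99.76th percentile. A lower yield of short, abundant transcripts was to be excluded if mitochondrial ribosomal, proteasome and small nuclear ribonucleoprotein genes all lay above the 2.5th percentile, and they did, at 5.08, 22.7 (median -0.04, mean 0.01) and 37.2. It is left open nonetheless, a reading adopted after these values were seen, because the first is near that bound, oxidative phosphorylation genes above background lay at the 1.25th percentile, and transcript lengths were not used here; a difference in growth between the cultures and an effect of the hairpin also stay open, untested.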

How the results depend on the processing

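No paired analysis was possible because each group held 1 array. For the same reason no replicate could be left out. Without a background filter 545 genes were higher and 440 lower; with both arrays above background 81 and 77; at 1.5-fold 958 and 588; at 3-fold 46 and 41; with the accessions of the second table alone, which name 3045 genes, 51 and 48. The other alternatives kept both counts within 1.5 times of 263 and 165. The share of higher genes among the calls, 61.4%, moved by over 10 percentage points with both arrays above background, to 51.3%. With the higher or the lower of the 2 background levels used for both arrays, chosen after seeing the data, the counts were 211 and 165 or 263 and 205, or 56.1% and 56.2% higher. It was 56.0% median-centred (228 and 179), 54.7% after quantile normalization (222 and 184) and 53.7% after loess (216 and 186), so the excess of higher genes depends on scaling as well as on the background level. TRPS1 stayed between -0.27 and -0.34 under the 6 alternatives that hold it and was under 2-fold in each. It has 1 feature, so only the rescalings among them could change its value. Of 370 alternatives for 74 named genes 361 stayed on the same side of 2-fold, 9 no longer reached it (ATF3, H2BC21, MCL1 and MUC1) and 0 reversed. Among these genes only ATF4, MUC1 and ZAP70 had more than 1 feature. For the others the rules on features repeat the main value, so those runs could not differ.

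Among the lists outside the range, mitotic and ribosomal protein genes stayed outside it under each alternative run, and HEK293 genes under each that held members. The HEK293 list had no member in the second table and was not run with its accessions. With both arrays above background it held 3 genes. Median-centring moves a list and its random lists alike, so it cannot change a percentile, and loess can change one only a little. With the accessions of the second table alone, which leave 1 to 7 members, the medians were 0.27 for YAP and TAZ targets, 0.43 for the 1 immediate early gene left, 0.11 for replication, 0.0204 for interferon and -0.40 for fatty acid genes, all inside the range, 0.39 for 2 histone genes, a reversed sign, and only 1 list lay below the range. The replication list came inside it at 0.18 with the feature of median difference. The unfolded protein response list came inside it at 0.28 with the accessions outside the second table and with unmatched random lists, and at 0.22 over members above background on 1 or on both arrays, where the interferon list had 0.17 and 0.16. The histone list came inside at -0.19 when gene span was matched as well, an alternative chosen after seeing the data. With means in place of medians 10 lists lay above the range. Apart from the fewer genes that some settings leave, the cause was not tested. Signal over background limits the rest: 270 of the 428 calls had a dim array.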

Other observations

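The genes, families and lists in this part were chosen after the largest differences had been seen.

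Keratins and S100 proteins differed in both directions. Of 20 keratin genes above background 2 were higher, KRT14 and KRT17, and 2 lower, KRT13 by 3.16-fold, from 10259 to 3243, and KRT81 by 2.87-fold, from 1391 to 484, while the abundant luminal keratins KRT8, KRT18 and KRT19 had log2 differences of -0.38, 0.14 and -0.05. Of 10 S100 genes above background S100A2 was higher, whereas S100A1 was 2.81-fold lower, from 1699 to 604, and S100P 2.67-fold lower, from 2127 to 796. Other genes with large differences and both arrays above background were ITM2A (3.25-fold higher), SOD3, an extracellular superoxide dismutase (2.96-fold higher), PLK2 (2.88-fold higher), ALDH3A1, an aldehyde dehydrogenase (3.46-fold lower), and CALML5, a calmodulin-like protein of differentiating epidermis (2.85-fold lower). For AHR and NRF2 target genes the median was 0.26 at the 92.7th percentile, with UGT1A1 higher and ALDH3A1 lower.

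Hypotheses on gene groups were tested on lists that left out genes behind them, except that ATF3, called already, stayed among the ATF4 targets. ATF4 itself was higher, and a candidate explanation for this group is a shared ATF4 response: 25 of its target genes had a median of 0.35 at the 99.8th percentile, and the 20 of them outside the unfolded protein response list 0.39 at the 99.9th percentile, while the 5 inside that list had 0.34 at the 85.4th, inside the range, and only ATF3 was called. A shift of p63 targets, of interest because KRT14, S100A2 and the chloride channel regulator CLCA2 are among them, was not shown: the 27 other p63 targets had a median of 0.21 at the 94.2th percentile, with FGFBP1 and ITGB1 called higher. A common fall of TNF superfamily and lymphocyte signalling genes, prompted by CD70, TNFRSF18, TRAF1, SLAMF1 and ZAP70, was not seen either, with a median of 0.002 at the 42.5th percentile over 22 other genes.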
